A study of Mus musculus with 18 samples.

How the data were processed

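Leukemia stem cells were sorted by flow cytometry from the bone marrow of C57BL/6JRj mice 30 days after leukemia was induced, with 7000 cells taken from each of 9 mice, per the labels. The labels put 5 mice in the Prx1-Cxcl12 mutant group and 4 in the control group, and give 2 technical replicate libraries for each mouse, 18 libraries in all. Libraries were made from polyadenylated RNA by the MARS-seq method, which reads the 3' ends of transcripts and was adapted to bulk RNA, and were run on a NextSeq 500, per the labels' protocols. The sorting markers, the leukemia driver, the sex of the mice and the days of harvest and library preparation are not given in the sources used here.

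The authors deposited one table of estimated counts, 54347 genes by 18 libraries. The submitters' processing notes name bcl2fastq, FastQC, Salmon 1.3 and the GRCm38 genome build, with no order or role. The annotation release, the use of molecular identifiers, the strand setting and the way transcripts were summed to genes are not given in the sources used here. Of all values, 11.3% were not whole, and no column had been scaled to a common total. The table lists Ensembl gene IDs, of which 11326 carried 1 or more digits beyond the 18 characters of an ID. The first 18 characters were matched to GENCODE mouse release 21, which gave a symbol for 54094 IDs. The 253 unmatched IDs held 0.00977% of the counts and were kept under their ID. Every column was used.

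The mouse was the unit of replication. The estimated counts of both libraries of a mouse were summed and rounded to whole numbers. Total counts ranged from 3825500 to 15071673 per library and from 11766467 to 25485899 per mouse. A level of 3 counts corresponded to 0.25 CPM in the shallowest mouse and to 0.12 CPM in the deepest. Intervals and floors of this kind cover counting error only.

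Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM factors, quasi-likelihood F-test, all 9 mice, no covariate), which kept 12973 genes. Fold changes are mutant over control, p-values are 2-sided and were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. A standard error is the unshrunk log2 coefficient divided by the square root of F. CPM values used TMM factors. Gene lists were tested with camera in limma 3.58.1 on voom weights with a preset inter-gene correlation of 0.01. A list's mean log2 fold change is that of the voom fit, whereas single genes carry edgeR values. Of 40 lists written, 35 were tested. The B and plasma cell, T and NK cell, megakaryocyte and platelet, and mast cell and basophil lists had fewer than 5 tested genes, and the sex-linked list served as a check of the samples. A list score per mouse is the mean over members of log2 CPM less the control mean. After the data had been seen, the scores of called lists and of the gene sets weighed below were also fitted by least squares on group with and without the centred log2 total count, for the SE of the score difference. Scores and 6 measures of library composition were compared by a 2-sided exact permutation test over the 126 splits of the mice, whose smallest possible p is 0.00794. Mouse numbers are not shared between groups and the labels give no pairing across groups, so none was used.

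The named genes were Cxcl12 and Cxcr4, the genes past the threshold, the 5 with the smallest p in each direction where fewer than 10 passed, the 4 members with the smallest p of each called list, and the 2 with the smallest p of each other energy, redox, niche and identity list. Predicted genes and pseudogenes were left out. If more than 12 genes had passed in a direction, the 12 most changed with a mean of at least 5 CPM would have been taken. Genes named outside this rule are marked as chosen after their values were seen. The groups, the tests, the lists, the naming rule and the alternatives, but for those named below, were fixed before the data were examined.

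Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, limma-voom on the mouse sums, no low-count filter, a filter at a mean of 10 CPM, each technical library alone, limma-voom on the 18 libraries with the mouse as a random effect with and without a technical replicate block, the 18 libraries taken as independent, the log2 total count as a covariate, a threshold of 0.1, and leaving out each mouse. For lists, an estimated correlation, fry and ranks were also tried. Thinning each mouse to the smallest total, and leaving out the first library of mutant mouse 7, were added after the data had been seen. Gene positions are from the GENCODE release on GRCm38.

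The edgeR step was tested on simulated data of the same depth, spread and group sizes, with 200 genes changed among about as many genes as were tested here. Of genes changed 1.5-fold, 21.9% were recovered, of those changed 2-fold 70.9%, and of those changed 3-fold 89.5%. False calls made up 3.31%, 6.13% and 5.67% of the calls. With no gene changed, 0.5 genes were called on average over 4 simulations. Each gene was drawn independently of the others, and simulated mice of a group differed in depth only. These rates therefore need not hold for the real data, where genes vary together. With no gene changed the simulations called 0 lists, whereas the other splits of the real mice described below called a median of 7. Figures were drawn with matplotlib.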

Results

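Cxcl12 encodes a chemokine that stromal cells of the marrow use to retain haematopoietic cells, and Cxcr4 encodes its receptor. The comparison addressed how the loss of Cxcl12 from Prx1-lineage stromal cells of the niche relates to the transcriptome of leukemia stem cells, with redox and energy genes as the stated interest. RNA was profiled in sorted cells of 5 mutant and 4 control mice. Total counts were 20734088 ± 4170598 in the mutant group (SD, n = 5) and 15160572 ± 2307737 in the control group (SD, n = 4), and each mouse is the sum of 2 technical libraries.

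Cxcl12 (ENSMUSG00000061353, GRCm38 chromosome 6, 117168535 to 117181367) was at or near the floor in the sorted cells of both groups. Control mice had 0, 0, 0 and 1 counts, and mutant mice had 1, 1, 2, 2 and 4 counts, against a floor of 3 counts per mouse, so no fold is given. These cells are not the cells that the Prx1 promoter targets, and their Cxcl12 level is no check of the deletion. Cxcr4 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293) was at 12.7 ± 3.51 CPM in controls (SD, n = 4) and 8.72 ± 2.75 CPM in mutants (SD, n = 5). Its log2 fold change of -0.53 (SE 0.23) did not pass, at an edgeR adjusted p of 0.465. The CXCR4 axis and adhesion list, with 13 of 19 members below 0, was not called either (camera adjusted p = 0.263), and its members with the smallest p were the integrin gene Itgal at 0.53 (SE 0.20) and the tetraspanin gene Cd9 at -0.29 (SE 0.12).

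Both cold-inducible RNA-binding protein genes, Rbm3 and Cirbp, were higher in the mutant cells. Rbm3 rose 2.28-fold, from 502.6 ± 113 to 1146 ± 154 CPM (SD, n = 4 and 5; log2 fold change 1.19, SE 0.16, edgeR adjusted p = 0.0368), and Cirbp rose 1.89-fold, from 13.3 ± 1.95 to 25.1 ± 3.51 CPM (0.92, SE 0.14, adjusted p = 0.0401). Ccdc122, a coiled-coil gene, rose from 2.70 ± 0.58 to 7.03 ± 1.11 CPM (1.37, SE 0.19, adjusted p = 0.0368). Among genes that fell were Fcnb, encoding the lectin ficolin B of the myeloid lineage (26.3 ± 4.92 to 11.04 ± 2.76 CPM, log2 fold change -1.26, SE 0.18), and Ctsh, encoding the lysosomal protease cathepsin H (145 ± 15.4 to 83.7 ± 13.6 CPM, -0.79, SE 0.12). A pair of integrin alpha genes fell, Itga1 (32.7 ± 4.03 to 20.3 ± 0.92 CPM, -0.69, SE 0.10) and the megakaryocyte and progenitor gene Itga2b (2.48 ± 0.45 to 0.67 ± 0.24 CPM, -1.89, SE 0.30).

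The other genes that fell were Chd3, a chromatin remodeller of the NuRD complex (9.65 ± 1.63 to 3.87 ± 0.84 CPM, -1.32, SE 0.18), and Nat8l, the synthase of N-acetylaspartate (11.7 ± 1.66 to 5.42 ± 1.22 CPM, -1.11, SE 0.17). Their edgeR adjusted p-values, and those of the 4 before them, lay between 0.0368 and 0.0427. In total 9 of 12973 genes were called, 3 higher and 6 lower in mutants, and for each of them the groups did not overlap. Over all genes, 519 had groups that did not overlap (4.0%, against 1.59% by chance), and 1278 had an unadjusted p under 0.05 where chance gives 649. The biological coefficient of variation was 18.7%.

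**Figure D1:**
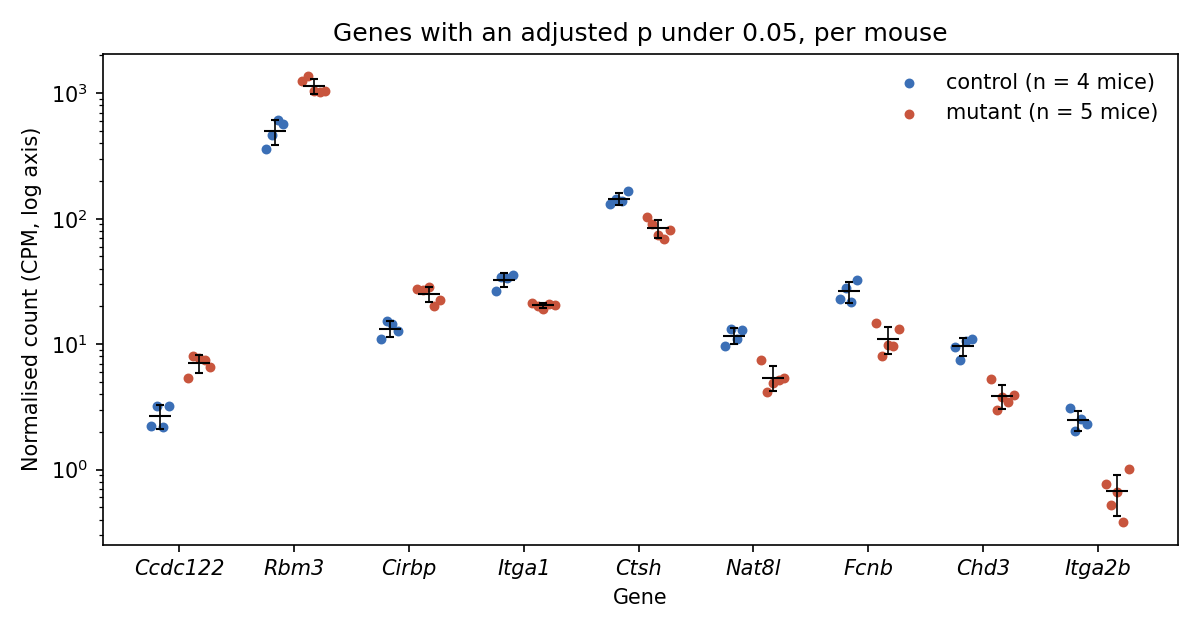
Normalised counts (CPM, log axis) of the 9 called genes in each of the 4 control and 5 mutant mice, where each point is a mouse and the bars give the mean ± SD. Rbm3 has a mean of 502.6 CPM in controls and 1146 CPM in mutants, and for every gene shown the points of one group lie apart from those of the other.

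By position on GRCm38, Rbm3 (ENSMUSG000000311676 in the table) lies on X, 8138975 to 8145880, and overlaps the antisense gene Rbm3os. Cirbp (ENSMUSG000000451933) lies on chromosome 10, 80165985 to 80172786, Fcnb (ENSMUSG000000268355) on 2, 28076378 to 28084885, Ctsh (ENSMUSG000000323594) on 9, 90054152 to 90076089, and Nat8l (ENSMUSG00000048142) on 5, 33995984 to 34005916, with no overlapping gene. Ccdc122 (ENSMUSG000000347954; 14, 77036772 to 77112257) overlaps Lacc1 on the opposite strand, and Itga1 (ENSMUSG000000422840; 13, 114953096 to 115101964) overlaps Gm49395 and Pelo on its own strand and Gm10734 on the opposite strand. Chd3 (ENSMUSG000000184748; 11, 69343273 to 69369406) and Itga2b (ENSMUSG000000346643; 11, 102453297 to 102470122) each overlap a small RNA gene. Counts of Rbm3, Ccdc122 and Itga1 are uncertain to the extent that reads of these neighbours were assigned to them.

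The genes next in order did not pass. Higher values in mutants were found for the histone gene Hist1h2ap (2778 to 4163 CPM, adjusted p = 0.0798), whose near-identical copies share reads, the metallothionein gene Mt2 (1.67 to 4.75 CPM, adjusted p = 0.112), Bok, Pla2g16 and Wfdc21. Lower values were found for Camp, the cathelicidin of neutrophil granules (386 ± 129 to 139 ± 47.7 CPM, log2 fold change -1.47, SE 0.27, adjusted p = 0.115), Klf13, Dennd5a, Fam129c and Tent5c. The 9 calls lay just inside the threshold, and leaving out a mouse gave 2 calls without control 1 (2 of them among the 9), 4 without control 2 (1 among the 9), 7 without mutant 6 (6 among the 9) and 0 without control 3 or 4 or mutant 7, 8, 10 or 12. Cirbp and Itga2b passed in 0 of these 9 sets. The 9 log2 fold changes kept their sign in each of them, with Rbm3 between 1.057 and 1.301. Groups that do not overlap keep their order when a mouse is left out, so the kept signs add no support. DESeq2 called 93 genes, the 9 among them.

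Genes of cell division stood higher in the mutant cells. In the G2 and M phase list, 42 of 43 members had a log2 fold change above 0, with a mean of 0.21 (camera adjusted p = 8.58e-13), and in the S phase list 32 of 34 did, with a mean of 0.14 (adjusted p = 3.71e-05). Both adjusted p-values were 0.31 with an estimated correlation. The kinase gene Aurkb had 138 ± 16.7 CPM in controls and 174 ± 8.44 CPM in mutants (log2 fold change 0.33, SE 0.10), the topoisomerase gene Top2a 0.29 (SE 0.09), and the kinetochore gene Ndc80 also 0.29 (SE 0.09). Of the S phase genes the smallest p-values belonged to Ccne2 at 0.48 (SE 0.18), Cdc45 at 0.22 (SE 0.08), Rfc4 and Rrm2. No single member of either list passed, over all genes or adjusted over the list alone. The S phase call ended in the first technical libraries alone (mean 0.075, adjusted p = 0.0526).

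The lists named for quiescence and for stem cell self-renewal stood lower. The quiescence list had 17 of 23 members below 0 (mean -0.22, camera adjusted p = 0.0206, and 0.359 with an estimated correlation), and 1 passed when adjusted over the list alone, the thioredoxin-binding protein gene Txnip (110 ± 10.6 to 86.9 ± 2.43 CPM, -0.34, SE 0.09). The cell cycle inhibitor gene Cdkn1b was at -0.52 (SE 0.18) and Btg2 at -0.62 (SE 0.24), whereas the inhibitor gene Cdkn1c was at 0.87 (SE 0.32). Furthest below 0 were the early response genes Jun (-1.22, SE 0.52), Klf4 (-0.97, SE 0.45) and Fosb (-0.85, SE 0.70), chosen after their values were seen. Fos was at -0.83 (SE 0.42) and Nr4a1 at -0.71 (SE 0.53), chosen likewise, while 6 of the 23 members were above 0. The list thus does not separate quiescence from an early response, and this was not tested. The self-renewal list had 17 of 24 members below 0 (mean -0.12, adjusted p = 0.0108, and 0.31 with an estimated correlation). Adjusted over the list alone, 2 of its members were lower, the transcription factor gene Gata2 (32.4 ± 7.53 to 18.7 ± 4.08 CPM, -0.80, SE 0.18) and the receptor gene Kit (25.6 ± 1.99 to 19.0 ± 2.45 CPM, -0.43, SE 0.11), and over all genes 0 were. Gata2 is also a mast cell gene, and Cpa3, a mast cell protease gene chosen after its values were seen, went from 4.63 ± 3.30 to 1.60 ± 0.50 CPM. The call of the quiescence list ended without control 1 (adjusted p = 0.0621), control 2 (0.153) or mutant 10 (0.0587), with a mean of -0.14 without control 1 and -0.09 without control 2. It also ended in the second technical libraries (mean -0.12, adjusted p = 0.314), with a mean of at least 10 CPM (mean -0.16, adjusted p = 0.118) and with the total count as a covariate (mean -0.25, adjusted p = 0.0526). The self-renewal call ended without mutant 10 (mean -0.08, adjusted p = 0.0587) and with the covariate (mean -0.14, adjusted p = 0.0526). Neither mean moved closer to 0 with the covariate, and the SE of the score difference over mice rose from 0.18 to 0.26 for quiescence and from 0.06 to 0.09 for self-renewal. The quiescence scores of controls 3 and 4 were -0.32 and -0.28, within the -0.42 to 0.04 of the mutants, while controls 1 and 2 had 0.27 and 0.34. In the same way Btg2 had 10.8 and 11.4 CPM in controls 1 and 2, and 5.11 and 5.81 CPM in controls 3 and 4. Dusp1, of the NF-kB list, had 11.6 and 13.7 CPM in controls 1 and 2, and 6.47 and 4.21 CPM in controls 3 and 4.

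Of the energy genes, those of the TCA cycle rose as a group. Of 23 members, 17 were above 0 (mean 0.12, camera adjusted p = 0.00698, and 0.31 with an estimated correlation), among them the fumarase gene Fh1 (0.32, SE 0.12), Idh3a (0.40, SE 0.17), Dlat and Mdh1. The ATP synthase list (13 of 16 above 0, mean 0.10, adjusted p = 0.0371) and the list of complexes II to IV (20 of 25 above 0, mean 0.08, adjusted p = 0.0444) were also called higher, with an adjusted p of 0.535 with an estimated correlation for both. Atp5a1 had 0.27 (SE 0.09), Cox6c 0.41 (SE 0.17) and Uqcrc1 0.20 (SE 0.10), while Atp5f1 had -0.18 (SE 0.10). The complexes II to IV and TCA cycle lists share 4 genes. The 12 genes encoded in the mitochondrial genome were below 0 (mean -0.45, adjusted p = 0.00997, and 0.535 with an estimated correlation), as for mt-Nd2 at -0.62 (SE 0.37) and mt-Cytb at -0.44 (SE 0.37), and mutant 7 held 0.0638% of its counts in these genes against 0.161% to 0.223% in the other mutants. Without mutant 7 the mean of this list was -0.15 (adjusted p = 0.316), without control 2 it was -0.33 (adjusted p = 0.0806), and in the first technical libraries it was -0.27 (adjusted p = 0.461). The ATP synthase call ended without control 1, 2 or 4 or mutant 6, 7, 8 or 10 (adjusted p of 0.0513 to 0.202), and that of complexes II to IV without control 1, 2 or 4 or mutant 6, 7 or 10 (0.0678 to 0.276), with means of 0.07 and 0.04 without control 1. Both also ended in the second technical libraries (mean 0.02, adjusted p = 0.607, and -0.03, adjusted p = 0.785) and with a mean of at least 10 CPM (0.0728 and 0.0537). The latter ended without the first library of mutant 7 as well (0.0827). With the total count as a covariate the means of the ATP synthase, complex II to IV and mitochondrially encoded lists were -0.04, 0.01 and -0.06, and their calls ended (adjusted p of 0.534, 0.83 and 0.783). The TCA cycle call held without each mouse. It ended with the covariate (mean 0.10, adjusted p = 0.0526), where the SE of its score difference over mice rose from 0.04 to 0.06.

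Complex I (28 of 37 members above 0, adjusted p = 0.0665), fatty acid oxidation (15 of 22 above 0, adjusted p = 0.0936), the mitochondrial ribosome (0.263) and glycolysis (0.683) were not called. Complex I was called without control 3 (mean 0.14, adjusted p = 0.00137) or mutant 12 (0.13, adjusted p = 0.00228) in the first technical libraries (0.18, adjusted p = 0.000253), after thinning to equal totals (0.09, adjusted p = 0.0375) and without the first library of mutant 7 (0.07, adjusted p = 0.0494). Without mutant 12 the mitochondrial ribosome (0.0371) and fatty acid oxidation (0.0464) were called, the latter also without control 4 (0.0449). In fatty acid oxidation, Cpt1a, which governs the entry of fatty acids into mitochondria, went from 9.59 ± 2.00 to 15.4 ± 2.39 CPM (0.68, SE 0.16) and passed only when adjusted over the list alone. Of the glycolysis genes, Ldha had 0.26 (SE 0.09) and the hexokinase gene Hk3 -0.25 (SE 0.09). At an unadjusted p under 0.05, 1 glycolysis gene was higher and 3 were lower. The fry mixed test, which counts changes in either direction, gave this list an unadjusted p of 0.0141.

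No redox list was called from all counts of the 9 mice without a covariate. The glutathione and thioredoxin genes went both ways, 21 of 32 above 0 and 11 below (camera adjusted p = 0.824), with the peroxiredoxin gene Prdx4 at 0.51 (SE 0.16) and Txnip at -0.34. Camera looks for a shift in a common direction, so its p does not exclude changes both ways. At an unadjusted p under 0.05, 3 members were higher and 4 lower, and the unadjusted fry mixed p was 0.0146. None passed when adjusted over the list alone. The superoxide dismutases and NRF2 targets had an adjusted p of 0.436, with the ferritin gene Ftl1 at -0.34 (SE 0.12) and Sesn2 at -0.42 (SE 0.17). Of the NADPH oxidase genes 7 of 8 were below 0 (mean -0.16, adjusted p = 0.0747), with Cybb, the catalytic subunit, at 50.5 ± 17.6 CPM in controls and 31.0 ± 10.9 CPM in mutants (-0.71, SE 0.27) and Ncf1 at -0.20 (SE 0.11). This list was called lower with the total count as a covariate (mean -0.21, adjusted p = 0.0321), after thinning (-0.21, adjusted p = 0.0436), and without mutant 7 (-0.20, adjusted p = 0.049). The HIF1 targets had 16 of 21 members below 0 (adjusted p = 0.0565), and were called without control 3 (0.019) or mutant 7 (0.0212), without the first library of mutant 7 (0.0174) and by camera on ranks (0.0418).

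**Figure D2:**
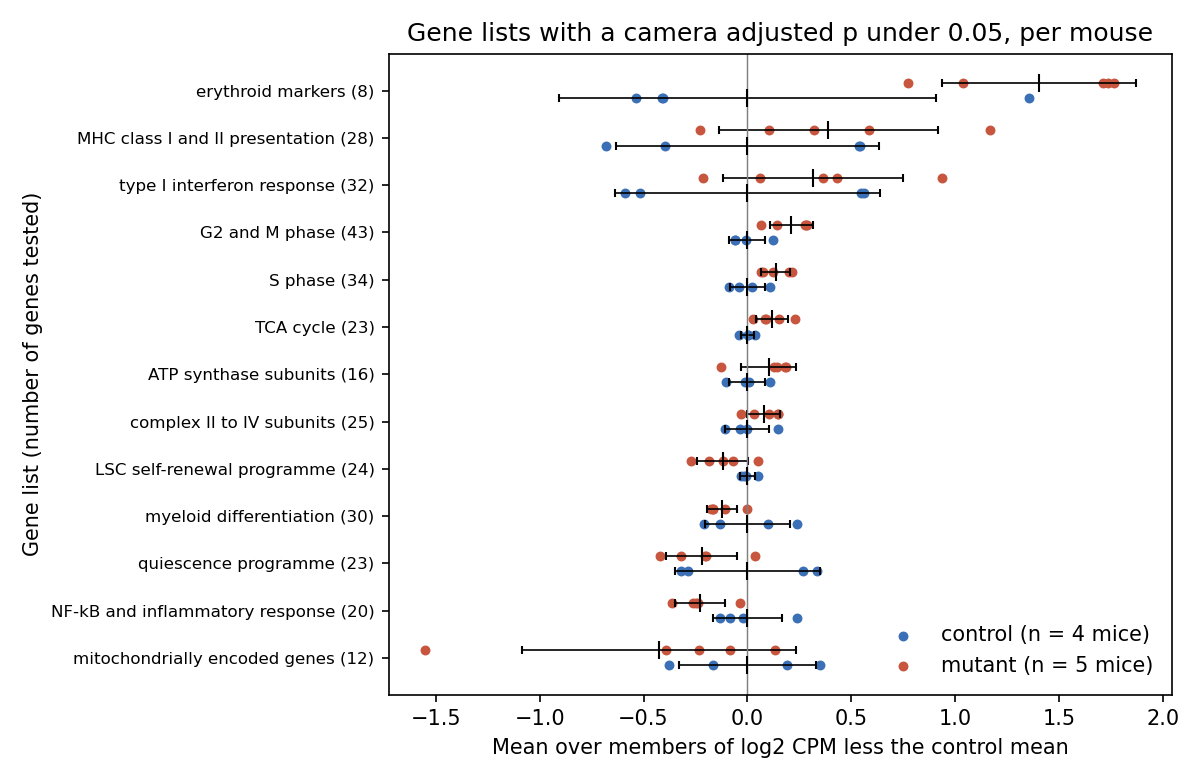
Mean over the tested members of log2 CPM less the control mean, for the 13 lists called by camera, in each of the 4 control and 5 mutant mice, with bars at the mean ± SD and the number of tested genes after each name. Mutant mice average 0.21 in the G2 and M phase list, and mutant 7 lies apart at -1.55 in the mitochondrially encoded list.

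NF-kB and inflammatory genes were lower as a group, with 17 of 20 below 0 (mean -0.25, camera adjusted p = 0.00698, and 0.31 with an estimated correlation), as for the early response genes Ier3 (-0.56, SE 0.18) and Dusp1 (-0.75, SE 0.30), Zfp36, and the NF-kB subunit gene Nfkb2 (-0.25, SE 0.10). The type I interferon list (23 of 32 above 0, mean 0.30, adjusted p = 0.0161) and the MHC class I and II list (23 of 28 above 0, mean 0.37, adjusted p = 0.013) were higher, with adjusted p-values of 0.691 and 0.66 with an estimated correlation. Ifit2 went from 4.68 ± 0.48 to 8.52 ± 1.95 CPM (0.87, SE 0.18), and was the 1 interferon gene to pass when adjusted over the list alone. In the MHC list the 4 members with the smallest p were Cxcl10 at 1.16 (SE 0.29), Gbp3 at 0.505 (SE 0.28), Gbp2, and B2m at 0.72 (SE 0.44). Cxcl10 is a chemokine gene and Gbp2 and Gbp3 encode interferon-induced GTPases, so this list is not one of antigen presentation alone. Gbp2 stood at 56.4 CPM in mutant 7 and between 2.59 and 16.4 CPM in the other mutants. The interferon call ended without control 1, control 3 or mutant 7 (adjusted p of 0.44, 0.51 and 0.324, mean 0.09, 0.10 and 0.11), in the second technical libraries (0.115) and with a mean of at least 10 CPM (0.0537), the MHC call without the same mice (0.52, 0.127 and 0.221, mean 0.16, 0.24 and 0.16), and the NF-kB call without control 2 (0.0554, mean -0.16). With the total count as a covariate the interferon and MHC means were -0.045 and -0.002, and both calls ended (adjusted p of 0.901 and 0.597).

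Genes of myeloid differentiation were lower as a group, with 20 of 30 below 0 (mean -0.12, camera adjusted p = 0.034, and 0.359 with an estimated correlation). Adjusted over the list alone, Camp and the granulocyte transcription factor gene Cebpe (195 ± 12.1 to 146 ± 24.1 CPM, -0.42, SE 0.12) were lower and the lactoferrin gene Ltf (4.82 ± 3.67 to 13.5 ± 4.43 CPM, 1.47, SE 0.39) was higher. Csf3r was at -0.51 (SE 0.17). The myeloid call ended without control 2 (adjusted p = 0.204, mean -0.04), control 4 (0.091), mutant 7 (0.0812) or mutant 12 (0.0723), in the first technical libraries (0.105) and by camera on ranks (0.0534).

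Markers of other cells were near the floor or mixed. Erythroid markers were higher, with 7 of 8 above 0 (mean 1.59, camera adjusted p = 0.000163, and 0.31 with an estimated correlation), and the carbonic anhydrase genes Car2 (0.75 ± 0.58 to 3.27 ± 0.52 CPM) and Car1 (0.24 ± 0.40 to 2.40 ± 1.08 CPM) and the globin gene Hbb-bt (0.90 ± 1.15 to 3.35 ± 1.88 CPM) passed when adjusted over the list alone. These genes together held 0.00305% ± 0.0022 of the counts in controls (SD, n = 4) and 0.00486% ± 0.0016 in mutants (SD, n = 5). The erythroid and cell division lists were both higher in the mutant group, but their scores did not go together in every mouse. Control 2 had an erythroid score of 1.36 and a G2 and M phase score of -0.006, and control 4 had -0.54 and 0.125. An association over mice was not tested. Macrophage markers (adjusted p = 0.0735) had 2 members lower when adjusted over the list alone, Adgre1 at -0.53 (SE 0.12) and Apoe at -0.48 (SE 0.13), named after their values were seen. They were called lower without control 1 (0.0498) or mutant 7 (0.0227). Mature neutrophil (0.812), dendritic cell (0.701) and stromal and endothelial markers (0.446) were not called. The neutrophil markers went both ways, which camera does not detect. Adjusted over the list alone, 2 of them were higher and 1 was lower. Their unadjusted fry mixed p of 5.61e-05 was the lowest of the tested lists. The lists too short to test held Ighm at -0.19 (SE 0.19) for B cells, Nkg7 at 0.10 (SE 0.20) for T and NK cells, and Gp9 at 0.17 (SE 0.21) for platelets, chosen after their values were seen. These single genes do not stand for their lineages. The megakaryocyte and progenitor gene Itga2b was called lower (-1.89, SE 0.30), and the mast cell gene Cpa3 was lower, as given above.

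Growth and stress genes gave no call. The cytosolic ribosomal proteins (adjusted p = 0.263), MYC targets (0.329), cholesterol synthesis (0.203), unfolded protein and integrated stress response (0.607), heat shock (0.185), p53 targets (0.812), apoptosis regulators (0.607), autophagy and lysosome (0.17) and TGF-beta and SMAD targets (0.16) were not called. In the last of these, Id1 (80.2 ± 4.45 to 63.4 ± 6.17 CPM, -0.34, SE 0.09) was lower when adjusted over the list alone. The ribosomal proteins were called higher without control 3 (mean 0.16, adjusted p = 2.08e-05) or mutant 12 (0.12, adjusted p = 0.00672) and in the first technical libraries (0.252, adjusted p = 1.28e-08). They were called lower in the second technical libraries (-0.119, adjusted p = 0.00143) and with the total count as a covariate (-0.115, adjusted p = 0.000928). Cholesterol synthesis was called higher without control 4 (0.0258) or mutant 8 (0.044). Of the 35 lists, 13 were called, 8 higher and 5 lower. With an estimated correlation 0 were called by camera and 5 had an unadjusted p under 0.05, and fry called 0 with 8 at an unadjusted p under 0.05 (lowest adjusted p = 0.114). Compared per mouse, 7 list scores had an exact permutation p under 0.05, and the lowest adjusted value was 0.238. Of the called lists these were TCA cycle (0.0238), G2 and M phase and NF-kB (0.0317 each), erythroid (0.0397) and S phase (0.0476). The others were fatty acid oxidation (0.0159) and NADPH oxidase (0.0476), which camera did not call. All remaining called lists had an exact permutation p between 0.119 (self-renewal) and 0.389 (interferon).

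Mutant libraries tended to be deeper. Total counts were higher by 5573517 on average (exact permutation p = 0.0556, adjusted p = 0.214), and genes with a count numbered 18380 ± 297 in controls and 19080 ± 502 in mutants (exact permutation p = 0.0714, adjusted p = 0.214). Mitochondrially encoded genes took 0.201% ± 0.050 of counts in controls and 0.162% ± 0.059 in mutants (exact permutation p = 0.341), ribosomal protein genes 29.4% ± 2.23 and 29.6% ± 0.87 (0.849), haemoglobin genes 0.0018% ± 0.0021 and 0.0032% ± 0.0016 (0.27), and the 10 most abundant genes 9.04% ± 0.47 and 8.82% ± 0.37 (0.46), each as SD with n = 4 and 5. Xist was at 150 to 230 CPM in the 9 mice and Ddx3y had at most 1 count.

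The 2 libraries of a mouse were only slightly more alike than libraries of different mice. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM had a median of 0.971 for the same mouse, 0.966 for different mice of a group and 0.964 between groups, and 8 of 18 libraries correlated best with their partner. The coefficient of variation was 17.4% within a mouse and 21.5% among libraries of a group. Rbm3 lay between 332 and 671 CPM in the 8 control libraries and between 881 and 1399 CPM in the 10 mutant libraries, and Cirbp between 9.81 and 17.0 CPM and between 17.6 and 31.2 CPM.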

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

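The tests of explanations in this part were chosen after the results they bear on had been seen. For clock genes, transcript length and the number of genes and lists in other splits, the expected outcomes were written before the test was run. The gap of 1 mouse to the nearest other mouse of its group was compared with the range of that group, for the named genes, the composition measures and the scores of the called lists. Of 212 groups of values, 18 had a mouse that stood apart, where chance gives about 10.6.

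Mutant mouse 7 stood apart most often. It held Gbp2 at 56.4 CPM (2.59 to 16.4 CPM in the other mutants), Rtp4 at 17.1 CPM (3.14 to 6.52), Atp5c1 at 519 CPM (396 to 413), Ldha at 527 CPM (417 to 438), Cxcr4 at 13.5 CPM (6.77 to 8.53), Csf3r at 36.7 CPM (59.4 to 67.4) and mt-Cytb at 58.5 CPM (217 to 258). Control mouse 2 stood apart in erythroid transcripts, with 0.00495% of counts in haemoglobin genes (0.000482% to 0.00103% in the other controls), Hbb-bt at 2.61 CPM (0.178 to 0.477), Car1 at 0.831 CPM (0 to 0.119) and an erythroid list score of 1.36 (-0.54 to -0.41). Control mouse 1 had Ldha at 359 CPM (377 to 379) and Ndc80 at 49.5 CPM (44.4 to 45.0). Control mouse 3 had Atp5f1 at 242 CPM (281 to 284) and Cd9 at 20.0 CPM (17.4 to 17.5). Mutant mouse 6 had Mrpl36 at 136 CPM (147 to 151) and Tent5c at 0.991 CPM (0.501 to 0.598), and mutant mouse 12 had an ATP synthase list score of -0.13 (0.13 to 0.19).

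Other splits of the 9 mice into 5 and 4 were tried, 100 in all with the real one. As many genes as the real 9 were called in 2 of the 100, the real split among them, which is under the share of 0.05 set for this count. Such a count cannot tell the genotype from another structure of the mice that partly follows the groups. The highest of the other splits called 156 genes. It set control 3 with mutants 6, 7, 8 and 10 against controls 1, 2 and 4 with mutant 12, and this points to a structure of the mice that crosses the groups. Only control 3 and mutant 12 change sides between this split and the real one. Its sets also lay on opposite sides of 0 on the first principal component of log2 CPM, the main axis of spread among the mice (22.2% of the variance). Mutant 7 lay close to the border there, at 0.18. Whether this structure adds to the 9 calls was not tested. For the gene lists, 5 of the 100 splits called at least the real 13, the highest other calling 16, so chance cannot be excluded for the number of lists.

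The rise of Rbm3 and Cirbp appears in every mutant library. Greater depth of the mutant libraries is argued against as the whole explanation, since the difference of the pair's mean score over mice was 1.06 (SE 0.14) and stayed at 0.814 (SE 0.147) with the total count as a covariate. Both calls ended there (adjusted p of 0.839 and 0.842), as the fold changes fell and their SEs rose, to 0.96 (SE 0.18) for Rbm3 and 0.68 (SE 0.16) for Cirbp, so a part that goes along with depth stays open. Thinning each mouse to the smallest total left the pair's mean log2 fold change at 1.083, against 1.052 from all counts. A different time of day of harvest remains a candidate explanation, as both genes follow body temperature and the daily cycle. The 12 tested clock genes, listed before their values were seen, had an unadjusted fry mixed p of 0.0183. Such a value is not particular to them: glycolysis (0.0141) and glutathione and thioredoxin (0.0146), which camera did not call, had lower fry mixed p-values. It is thus weak support for this explanation. Among the clock genes, Per2 was at -0.56 (SE 0.18), Dbp at -0.44 (SE 0.14) and Tef at -0.38 (SE 0.18). The other 6 of the 9 clock genes at 5 CPM or more lay within 0.3 of 0, as for Per3 at -0.02 (SE 0.13), Cry1 at -0.01 (SE 0.10), Cry2 at -0.01 (SE 0.12) and Per1 at -0.15 (SE 0.16). None of the clock genes passed over all genes, and a change of the clock or of temperature signals by the genotype, which would give the same values, was not tested. Colder handling of the mutant samples cannot be told apart from the groups, as the heat shock list had a mean of -0.107 that did not pass (camera adjusted p = 0.185).

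For the higher cell division genes, 3 technical explanations were weighed. Depth is argued against as the whole explanation by a difference of their mean score over mice of 0.159 (SE 0.047) with the total count as a covariate, against 0.178 (SE 0.033) without it, though for the G2 and M phase list alone it went from 0.212 (SE 0.064) to 0.157 (SE 0.088), and a part that goes along with depth stays open. Thinning each mouse to the smallest total left the mean log2 fold change of these genes at 0.173, against 0.178 from all counts. Erythroid cells in the sort would need a share of counts far above the 0.00486% that their marker genes hold in mutants. A single mouse is argued against because the G2 and M phase list was called in 9 of the 9 sets that leave out a mouse. A structure of the mice that crosses the groups was not weighed for these genes. In the split that called 156 genes, the G2 and M phase list was called as well (mean 0.156, camera adjusted p = 1.92e-05). The S phase list was not called there (mean 0.01, adjusted p = 0.516). Over the splits of the mice the G2 and M phase score had an exact permutation p of 0.0317 (adjusted p = 0.238). The biological difference of genotype, which may act on the cell cycle, remains a hypothesis.

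The mitochondrial pattern splits in 2 parts. The lower mitochondrially encoded genes are consistent with a single mouse, as the mean moved from -0.448 to -0.151 without mutant 7. For the higher ATP synthase and complex II to IV genes, with a mean of 0.09, a difference between mice that does not follow the groups stays open, since a difference of their score as large arose in 26 of all splits of the mice into 5 and 4 (exact permutation p = 0.206). Traits that go along with depth, and short transcripts, stay open as well. The difference of the score was 0.089 (SE 0.064) and became -0.01 (SE 0.073) with the total count as a covariate. Thinning each mouse to the smallest total instead left the mean at 0.09, against 0.087 from all counts, and both lists stayed called. The number of counts as such is therefore argued against. After subtracting a trend on transcript length and level the mean was 0.063 (SE 0.026), which lies within 1 SE of the bound of 0.0433 set for it. Unlike the SEs of the score, this SE is over the 41 genes, which vary together, and not over mice. Genotype was not excluded for either part.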

How the results depend on the processing

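The 9 called genes kept their sign in 212 of 212 values over the alternatives and left-out mice, and were past the threshold in 98, with an adjusted p between 4.89e-10 and 0.839 for Rbm3. They were selected in these same mice, where their groups did not overlap, so the kept signs add little support. Against 9 genes, DESeq2 called 93 (the 9 included), no low-count filter 21, limma-voom on the 18 libraries with the mouse as a random effect 62, the same with a technical replicate block 58, and the 18 libraries taken as independent 141. No gene was called (0) by edgeR with a mean of at least 10 CPM (801 at an unadjusted p under 0.05), in the first technical libraries (996), with the log2 total count as a covariate (572) or without the first library of mutant 7 (1214), and 3 were called in the second technical libraries. Single technical libraries hold fewer counts, and the filter at 10 CPM removed Chd3, Ccdc122, Nat8l and Itga2b. The cause was not tested otherwise. Leaving out each mouse gave 0 to 7 genes. RLE and upper-quartile factors and limma-voom on the mouse sums each called the same 9, and thinning, added after the data had been seen like the library left out, called 6 of them. The technical replicate block changed the count from 62 to 58. The labels give no pairing of mice across groups.

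Against 13 lists, camera with an estimated correlation and fry called 0, the filter at 10 CPM 8 and the total count as a covariate 7, and the sets without a mouse 7 to 16. The covariate ended the calls of the TCA cycle (mean 0.101, against 0.118 without it), self-renewal (-0.14, against -0.12) and quiescence (-0.248, against -0.216) lists, each at an adjusted p of 0.0526. It also ended those of the mitochondrially encoded (-0.062, against -0.448), complex II to IV (0.014, against 0.076), ATP synthase, interferon and MHC lists, the last 3 with a reversed sign. The G2 and M phase list and the erythroid list, where enough of its genes were tested, were called in each alternative but those with an estimated correlation and fry.

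Signs that reversed mostly belonged to values near 0 that were not called, and the cause was not tested. With the total count as a covariate, which itself differs between the groups, the mean log2 fold change was -0.066 for complex I, -0.042 for ATP synthase, -0.023 for glycolysis, -0.046 for the mitochondrial ribosome, -0.054 for glutathione and thioredoxin, -0.115 for cytosolic ribosomal proteins (adjusted p = 0.000928), -0.035 for cholesterol synthesis, 0.034 for the unfolded protein response, -0.045 for type I interferon, -0.002 for MHC, 0.001 for TGF-beta targets, -0.155 for dendritic cell and 0.054 for stromal markers, and single genes gave -0.065 for Atp5j2 and -0.266 for B2m. In the second technical libraries it was -0.017 for complex I, -0.026 for complexes II to IV, -0.002 for glutathione and thioredoxin, -0.119 for cytosolic ribosomal proteins (adjusted p = 0.00143), 0.012 for TGF-beta targets and 0.048 for Atp5f1. In the first technical libraries cytosolic ribosomal proteins had 0.252 (adjusted p = 1.28e-08), opposite in sign to the second, and the mean was 0.002 for the unfolded protein response, 0.046 for p53 targets, 0.064 for mt-Nd5 and 0.049 for mt-Cytb. With the filter at 10 CPM it was 0.020 for the unfolded protein response, 0.019 for p53 targets and -0.323 for neutrophil markers. Thinning gave 0.038 for stromal markers, and leaving out the first library of mutant 7 gave 0 for neutrophil markers.

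Leaving out each mouse gave -0.107 to 0.008 for TGF-beta targets, -0.06 to 0.131 for cholesterol synthesis, -0.004 to 0.159 for cytosolic ribosomal proteins, -0.07 to 0.559 for dendritic cell markers, -0.013 to 0.057 for glutathione and thioredoxin, -0.213 to 0.333 for neutrophil markers and -0.172 to 0.008 for stromal markers. For composition, mutant minus control, it gave -0.274 to 1.31 percentage points for ribosomal protein genes and -0.365 to 0.0021 for the 10 most abundant genes. The first technical libraries gave 0.0041 for mitochondrially encoded genes and the second -1.4 for ribosomal protein genes. In the shallowest mouse 0.25 CPM corresponded to 3 counts, so lower levels were poorly measured there. A gene below that level in only 1 group could still differ, as for Car1 at 0.24 CPM in controls and 2.40 CPM in mutants.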

Other observations

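Immunoglobulin kappa transcripts marked 1 library. Igkc, chosen after its values were seen, had 620 counts in the first library of mutant mouse 7 and 1 count in the second library of the same mouse, with 0 to 12 counts in the other 16 libraries. Immunoglobulin genes together held 193 CPM in that library and 88.1 CPM in its partner, against 86.9 to 190 CPM in the other libraries. Without that library 0 genes were called by edgeR and 1214 had an unadjusted p under 0.05, and 14 lists were called.

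Of the genes in the split of the mice with the most calls, 116 were higher and 40 lower in the set of control 3 and mutants 6, 7, 8 and 10. The lists called in it were led by the cytosolic ribosomal proteins (mean log2 fold change 0.27, camera adjusted p = 2.35e-18), complex I (0.23, adjusted p = 7.71e-09) and the ATP synthase subunits (0.21, adjusted p = 3.74e-06). Other lists that were called between the real groups were called here too. These were G2 and M phase (0.156, adjusted p = 1.92e-05), complexes II to IV (0.156, 1.94e-05), quiescence (-0.257, 0.0145), mitochondrially encoded (-0.426, 0.02) and erythroid (1.001, 0.0473). The called higher genes had a median transcript length of 702 bases, the called lower genes 614 bases, and all tested genes 1292 bases. Across genes, which are not independent replicates, Spearman's rho between transcript length and log2 fold change was -0.155 in this split and -0.048 between the real groups. The split was drawn at random and its sets are not groups of the study.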
